A study of Arabidopsis thaliana with 24 samples.

How the data were processed

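The deposited table held 1 signal intensity per probe set and array, which the authors computed with GCOS 1.4 per the submitters' processing notes. The arrays were treated as already scaled, because trimmed means without the lowest and highest 2% of values ran from 100.1 to 101.4 between arrays, a ratio of 1.01 against a limit of 1.1 set beforehand. Signals were used as log2 of the value plus 1, the pseudocount being the 10th percentile of all values (1.2) rounded. Labels gave blue light as 35 µmol per s per m2, ABA as 0.5 with the unit written um, and 5 µg of total RNA per sample, extracted with Trizol and labelled as biotin cRNA.

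Of 22810 probe sets, 64 controls were set aside and 16196 were tested whose mean passed the 40th percentile of all values (19.1, called the dim level) in at least 1 group. R 4.3.3 with limma 3.58.1 fitted the means of 12 groups, of 2 arrays each, with empirical Bayes moderation (trend and robust). Adjusted p-values follow Benjamini and Hochberg within each comparison, with a threshold of 0.05. Comparisons were blue light against darkness and ABA against blue light in each genotype, atmyc2 and cop1-6 against WT and the double mutant against cop1-6 in each condition, the differences of the light and ABA responses from WT, and the atmyc2 by cop1-6 interaction in each condition. Groupings, comparisons, lists, the named-gene rule and the alternatives were chosen before the data were seen, except as stated below. The fit was tested on simulated data with 100 probe sets changed by a log2 of 1 and 100 by 2. It recovered 35% and 82% for atmyc2 against WT in blue light (9 false calls in 15996 unchanged). For cop1-6 against WT with ABA it was 40% and 82% (10). The latter may not hold, as the cop1-6 ABA pair was the least alike.

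Genes were named from the supplied probe and gene tables, with TAIR10.1 used for names only. The annotation gave 13513 probe sets 1 gene, 503 several genes and 8794 none. A gene in this text is a tested probe set with 1 gene, of which there were 8821, and 1225 carried a symbol other than the locus code. A named gene was read as one with such a symbol, which was decided after the annotation was seen. Named were MYC2 and COP1 (0 listed probe sets), the 5 highest and 5 lowest named genes of each comparison between genotypes and of the WT responses whose arrays did not overlap, members of lists that passed or held at least 3 called members, and the 3 highest and 3 lowest per interaction. The responses of the mutants are described by counts and lists.

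Lists comprised 24 fixed by name with 444 loci, and the plastid-encoded and mitochondrial genes. These last were matched by chromosome and by symbol, since the planned locus prefixes were absent from the annotation. Lists with at least 3 measured members were tested with camera of limma at a preset correlation of 0.01, which left 16. A further 8 had 1 or 2 measured members and 2 had no measured member, and these were not tested. Camera was also run with an estimated correlation. Another 36 families by symbol stem and 8 plastid subgroups were added after the annotation was seen, giving 142 calls, of which 6 held with an estimated correlation.

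Alternatives were no pseudocount, a pseudocount at the 40th percentile, no dim filter (22746 probe sets), a filter at the 60th percentile (56.5, 12287 probe sets), quantile normalization, moderation without trend and robust, a replicate block, only the arrays of the groups compared, and each array left out in turn. List tests in comparisons that use cop1-6 with ABA were rerun with each of its arrays left out, which was chosen after the data were seen. Overlaps were set against simulated data that keep the shared arrays. Raw probe-level files were not used here.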

Results

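Transcript levels were measured on 24 Affymetrix arrays, 1 per RNA sample of 10-day-old Columbia seedlings grown at 22 °C. Wild type (WT), atmyc2, cop1-6 and the atmyc2 cop1-6 double mutant were each grown in darkness, in blue light, or in blue light with abscisic acid (ABA), with 2 biological replicates (rep) per group. AtMYC2 is a basic helix-loop-helix transcription factor of light, ABA and jasmonate signalling, and COP1 is an E3 ubiquitin ligase that represses photomorphogenesis in darkness. The comparisons addressed what blue light and ABA changed in each genotype, what each mutation changed in each growth condition, and whether the effect of one mutation depended on the other. Of 22810 probe sets, 16196 were tested after dim ones were left out. The median signal of an array ran from 26.7 to 41.3 and the highest from 4701 to 10005.3. Genes, named from the supplied annotation, are given with the mean signals of n = 2 arrays per group and the limma log2 fold change ± SE. Gene lists are given with the members that passed over all probe sets, those adjusted over the list alone where that differs, the median log2 fold change and the adjusted p of limma's camera list test. Where a mean lay below the dim level of 19.1, the fold depends on the pseudocount (pc), and the fold at pc 19.1 is given as well if it differed by more than 1.5 times. Highest and lowest genes were ranked at pc 1, and ranks that rest on means under the dim level need not hold at pc 19.1. Whether the replicates came from separate cultures is not stated, so every p-value measures only the spread between these samples, which may be technical, and the small number of arrays limits the precision of every estimate.

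Replicates correlated with r from 0.914 to 0.986 on the log2 scale, across genes that are not independent replicates. The lowest value was that of the cop1-6 pair with ABA, whose arrays differed more than 2-fold at 1978 probe sets. Replicate 1 of that pair was closest to rep 2 of the double mutant with ABA (r = 0.973), and rep 2 to rep 1 of WT with ABA (r = 0.942). The blue light arrays of WT, atmyc2 and the double mutant and cop1-6 dark rep 2 were also closest to another genotype. Spike-in poly-A controls averaged 3.68 to 11.5 in blue light and 71.4 to 118 with ABA. In darkness they read 551 to 640.3 (WT, atmyc2) and 141 to 215 (cop1-6, double mutant). The 25S ribosomal RNA probe set read 28.5 to 96.3 in blue light, 769.5 to 2763 with ABA and 4.6 to 189.9 in darkness. The log2 ratio of 3 prime to 5 prime GAPDH control signals, a sign of RNA quality, was -0.32 and -0.33 on the dark WT arrays and -0.27 to 0.08 on the others. Batch and growth condition thus cannot be told apart in the light and ABA comparisons, nor batch and genotype in darkness between lines with and without cop1-6.

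**Figure D1:**
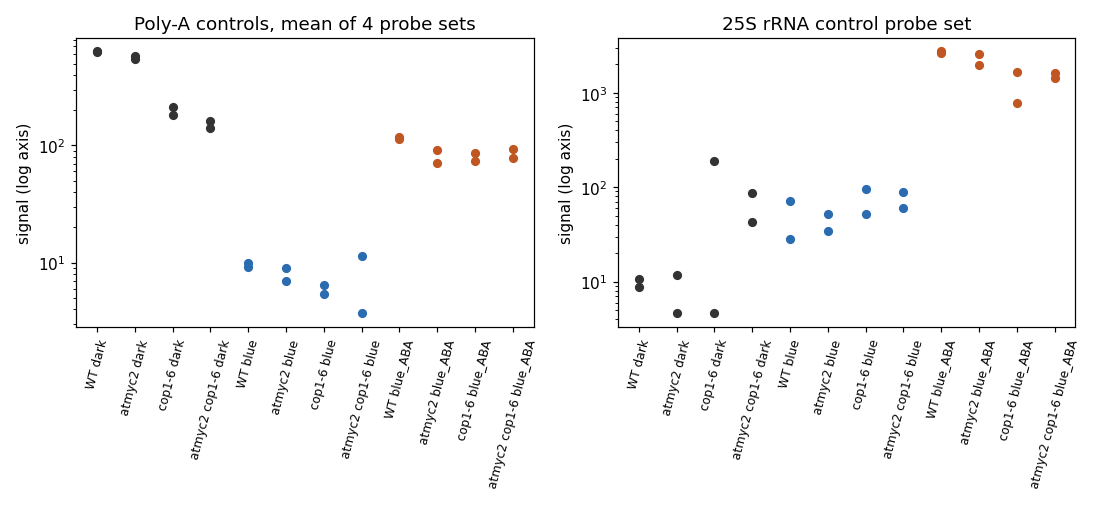
Signal of the spike-in poly-A controls (left, mean of 4 probe sets) and of the 25S ribosomal RNA probe set (right) on each array, by group, on log axes. Colours separate darkness, blue light and blue light with ABA.

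No probe set is listed under MYC2 or COP1 in the annotation used, so neither gene was analysed by name. A probe set without a gene in the annotation, chosen after its values were seen, separated the genotypes and serves here as the marker probe set. It read 91.7 to 251 on the 12 arrays with a wild-type AtMYC2 background and 0.3 to 15 on the 12 arrays carrying atmyc2. It was lower in atmyc2 than in WT in blue light (log2 -4.74, -2.71 at pc 19.1) and with ABA (log2 -3.91, -2.89 at pc 19.1). It was lower in the double mutant than in cop1-6 in blue light (log2 -4.65, -2.96 at pc 19.1).

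The first question was what growth in blue light changed in WT relative to darkness. ECS1, AT1G31580 (0.9 to 2392, log2 10.31 ± 0.37, 6.87 at pc 19.1, adjusted p = 5.88e-13) ranked highest of the named genes in WT. Next at pc 1 were the plastid-encoded photosynthesis genes atpF, ArthCp008 (9.65 to 1557, log2 7.19 ± 0.29, 5.77 at pc 19.1), a subunit of ATP synthase, and the photosystem II genes psbB, ArthCp049 (4.9 to 684, log2 7.05 ± 0.84, 4.68 at pc 19.1) and psbT, ArthCp050 (1.5 to 249, log2 6.53 ± 0.62, 3.56 at pc 19.1). MSRB6, AT4G04840 (2.5 to 284, log2 6.42 ± 0.26, 3.81 at pc 19.1), a methionine sulfoxide reductase, was among the highest 5 too. Falling most were ICL, AT3G21720 (899.5 to 19.8, log2 -5.53 ± 0.62, adjusted p = 2.88e-06), the isocitrate lyase of the glyoxylate cycle, and the RING finger gene ATL8, AT1G76410 (2708 to 140.4, log2 -4.30 ± 0.69). Next were the subtilisin-like protease gene ATSBT5.2, AT1G20160 (875 to 49.8, log2 -4.14 ± 0.26), the methionine gamma-lyase gene MGL, AT1G64660 (2120.0 to 182, log2 -3.58 ± 0.39) and RSU1, AT3G48130 (38.5 to 4.05, log2 -3.33 ± 0.88, -1.32 at pc 19.1). RSU1 lost its call without WT blue rep 2 (adjusted p = 0.0851). The GAPDH ratio was -0.32 and -0.33 on the dark WT arrays and -0.06 and -0.09 on the blue light ones.

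Among gene groups, plastid-encoded genes rose in WT in the light (64 of 67 higher, median 3.93, adjusted p = 3.38e-33, adjusted p = 0.0204 with an estimated correlation). Nuclear photosystem core genes rose as well (4 of 4 higher, median 4.1, adjusted p = 1.67e-06), among them PSAN, AT5G64040 (40.8 to 2449.8, log2 5.88 ± 0.15, 5.37 at pc 19.1) of photosystem I. With an estimated correlation the list test gave adjusted p = 0.0204. Chlorophyll synthesis rose (7 of 7 higher, median 2.07, adjusted p = 3.57e-06), with CHLI2, AT5G45930 (9.6 to 139, log2 3.86 ± 0.45, 2.45 at pc 19.1) and HEME2, AT2G40490 (35.5 to 282, log2 2.96 ± 0.20), which encode a magnesium chelatase subunit and uroporphyrinogen decarboxylase. Tested with an estimated correlation, the list gave adjusted p = 0.0274. Calvin cycle genes rose (3 of 3 higher, median 4.01, adjusted p = 5.17e-05), including SBPASE, AT3G55800 (38.8 to 1463, log2 5.20 ± 0.20) and PRK, AT1G32060 (120.1 to 1946, log2 4.01 ± 0.22). The list test gave adjusted p = 0.0274 with an estimated correlation. Photorespiration rose (3 of 3 higher, median 2.84, adjusted p = 0.00312) with HPR, AT1G68010 (179 to 2618, log2 3.86 ± 0.21), the hydroxypyruvate reductase, and so did glucosinolate synthesis (4 of 4 higher, median 3.51, adjusted p = 9.61e-04) with BCAT4, AT3G19710 (53.3 to 904, log2 4.11 ± 0.24), an aminotransferase of methionine-derived glucosinolates. Camera gave adjusted p = 0.0622 and 0.0739 with an estimated correlation. The antenna genes LHCB4.1 to LHCB4.3 were higher (3 of 3 higher, median 0.92, adjusted p = 0.0274, adjusted p = 0.145 with an estimated correlation), for instance LHCB4.2, AT3G08940 (632 to 2557, log2 1.98 ± 0.21). Expansins and XTHs did not pass as a group (3 of 5 lower, median -1.12, adjusted p = 0.277), while EXPA4, AT2G39700 (1556 to 557, log2 -1.51 ± 0.31) was lower. In total 3841 probe sets were higher and 3597 lower in blue light by limma (3584 and 3923 after quantile normalization).

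Each mutant was also compared between blue light and darkness. In atmyc2, plastid-encoded genes rose (52 higher and 1 lower of 67, median 2.59, adjusted p = 6.98e-12), as did nuclear photosystem core genes (4 of 4 higher, median 3.86, adjusted p = 6.61e-05). Read with an estimated correlation, these lists gave adjusted p = 0.118 and 0.0706. Chlorophyll synthesis (7 of 7 higher, median 2.75, adjusted p = 2.99e-04) and Calvin cycle genes (3 of 3 higher, median 5.68, adjusted p = 2.99e-04) rose too. Estimating the correlation instead gave adjusted p = 0.118 and 0.0957. Glucosinolate synthesis rose in atmyc2 (4 of 4 higher, median 3.72, adjusted p = 0.00152), and photorespiration rose (3 of 3 higher, median 3.11, adjusted p = 0.0127). In the same test with an estimated correlation, adjusted p = 0.118 and 0.118. Mitochondrial genes fell (1 higher and 8 lower of 14, 1 higher and 9 lower adjusted over the list alone, median -1.36, adjusted p = 0.0147), and expansins and XTHs stayed short of the list test (3 of 5 lower, median -1.83, adjusted p = 0.0505). The list call became adjusted p = 0.518 with an estimated correlation. By limma 5574 probe sets were higher and 3286 lower in atmyc2 (4288 and 4095 after quantile normalization, 51.2% higher against 62.9%), and quantile normalization lowered the median log2 by 0.27.

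In cop1-6 the plastid-encoded rise was smaller (35 higher and 2 lower of 67, median 0.56, adjusted p = 0.00943), beside Calvin cycle (3 of 3 higher, median 2.53, adjusted p = 0.0122) and photosystem core genes (4 of 4 higher, median 1.11, adjusted p = 0.0398). An estimated correlation gave adjusted p = 0.521, 0.463 and 0.463. The GAPDH ratio went from -0.10 and -0.06 to -0.18 and -0.22. The ubiquitin ratio went from -0.05 and 0.12 to 0.25 and 0.27. Other cop1-6 groups held called members without passing the list test, namely flavonoids (4 of 7 higher, median 1.79, adjusted p = 0.051 and 0.0348 after quantile normalization) and photorespiration (3 of 3 higher, median 0.97, adjusted p = 0.141 and 0.0488 after quantile normalization). Expansins and XTHs did not pass (1 higher and 3 lower of 5, median -2.30, adjusted p = 0.268), nor did ABA-responsive effectors (3 of 4 higher, median 1.43, adjusted p = 0.268) and mitochondrial genes (1 higher and 3 lower of 14, median -0.24, adjusted p = 0.483). The double mutant gained plastid-encoded (40 of 67 higher, 44 higher adjusted over the list alone, median 1.01, adjusted p = 1.01e-07) and Calvin cycle transcripts (3 of 3 higher, median 2.87, adjusted p = 3.32e-04). It also gained photosystem core (4 of 4 higher, median 1.36, adjusted p = 3.32e-04) and antenna transcripts (3 of 3 higher, median 0.93, adjusted p = 0.00951). Flavonoid genes also rose in the double mutant (5 of 7 higher, 6 higher adjusted over the list alone, median 2.33, adjusted p = 0.00878), as did photorespiration (2 of 3 higher, median 1.45, adjusted p = 0.0286). An estimated correlation gave, in order, adjusted p = 0.194, 0.081, 0.081, 0.173, 0.194 and 0.194. Its defensin branch (3 of 3 higher, median 2.66, adjusted p = 0.0628) and chlorophyll synthesis (4 of 7 higher, median 0.66, adjusted p = 0.0969 and 0.041 after quantile normalization) did not pass as groups. By limma 4951 probe sets were higher and 3809 lower in cop1-6 (4106 and 4323 after quantile normalization). In the double mutant 3231 were higher and 3147 lower (2891 and 3501 after quantile normalization), and the total was 4195 without atmyc2 cop1-6 dark rep 2. Quantile normalization lowered the median log2 by 0.15 in cop1-6 and 0.10 in the double mutant.

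Light responses were tested as differences from WT, which for cop1-6 and the double mutant cannot be told apart from batch. Plastid-encoded genes gained less in all 3 mutants than in WT. The list passed in atmyc2 (35 of 67 below 0, 38 below 0 adjusted over the list alone, median -1.38, adjusted p = 1.88e-30, adjusted p = 0.0549 with an estimated correlation). It also passed in cop1-6 (54 of 67 below 0, 55 below 0 adjusted over the list alone, median -3.02, adjusted p = 1.37e-27) and the double mutant (53 of 67 below 0, 56 below 0 adjusted over the list alone, median -2.88, adjusted p = 8.67e-29). Camera gave adjusted p = 0.0381 and 0.0332 with an estimated correlation. In darkness these genes stood higher in the mutants, and ndhG went from 195.5 to 103 in cop1-6 (difference from WT -6.79 ± 0.88, -4.04 at pc 19.1). The shared dark WT arrays had GAPDH ratios of -0.32 and -0.33. Nuclear photosystem core genes also gained less in cop1-6 (4 of 4 below 0, median -3.11, adjusted p = 1.49e-06) and in the double mutant (4 of 4 below 0, median -2.62, adjusted p = 1.23e-06), led by PSAN (log2 difference -4.45 ± 0.22, and -4.24 ± 0.22). Read with an estimated correlation, these lists gave adjusted p = 0.0241 and 0.0229. Chlorophyll synthesis (6 of 7 below 0, 7 below 0 adjusted over the list alone, median -1.77, adjusted p = 5.12e-06) and the Calvin cycle (3 of 3 below 0, median -2.41, adjusted p = 0.00157) lay below the WT response in cop1-6. Estimating the correlation instead gave adjusted p = 0.0397 and 0.0775. Glucosinolate synthesis (3 of 4 below 0, median -2.69, adjusted p = 0.0068) and photorespiration (2 of 3 below 0, median -1.49, adjusted p = 0.0287, adjusted p = 0.0996 after quantile normalization) did so as well. In the same test with an estimated correlation, adjusted p = 0.138 and 0.138. In the double mutant, chlorophyll (7 of 7 below 0, median -1.78, adjusted p = 5.05e-06) and glucosinolate synthesis (3 of 4 below 0, median -2.65, adjusted p = 0.00196) lay below WT. The list calls became adjusted p = 0.0396 and 0.112 with an estimated correlation. The Calvin cycle (3 of 3 below 0, median -2.12, adjusted p = 0.00196) and photorespiration (2 of 3 below 0, median -1.28, adjusted p = 0.0223, adjusted p = 0.063 after quantile normalization) did too. An estimated correlation gave adjusted p = 0.1 and 0.131. Seed-reserve mobilisation lay above WT in cop1-6 (3 of 3 above 0, median 1.24, adjusted p = 0.0286), as did ICL (4.03 ± 0.87), while salicylate defence did not pass as a group (3 of 3 above 0, median 1.60, adjusted p = 0.121). With an estimated correlation the list test gave adjusted p = 0.0775. Auxin response in the double mutant did not pass (2 above 0 and 1 below 0 of 5, median -0.66, adjusted p = 0.926 and 0.965 with the direction reversed after quantile normalization, with a mean log2 of -0.40 and a list test pointing upward). Mitochondrial genes lay below WT in atmyc2 (0 of 14 past the test, 3 at an unadjusted p under 0.05, median -0.57, adjusted p = 0.016, adjusted p = 0.864 with an estimated correlation). By limma, 2843 probe sets were above and 2790 below the WT response in cop1-6 (2485 and 2987 after quantile normalization), and 1811 and 2490 in the double mutant. For atmyc2 the counts were 774 and 512 (331 and 431 after quantile normalization, 43.4% higher against 60.2%, with the median log2 lowered by 0.16), and the total was 588 with only the arrays compared, 850 without WT dark rep 1, 698 without WT dark rep 2, 653 without atmyc2 dark rep 1, 599 without atmyc2 dark rep 2, 307 without WT blue rep 1, 3004 without WT blue rep 2 and 308 without atmyc2 blue rep 2.

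ABA was given to seedlings in blue light, and its effect in WT was read against blue light alone. ICL (19.8 to 5003, log2 8.03 ± 0.62, adjusted p = 4.93e-07) rose most of the named genes. Late embryogenesis abundant and cold-regulated genes came next, namely LEA18, AT2G35300 (1.55 to 660.4, log2 8.03 ± 0.75, 5.04 at pc 19.1), COR15A, AT2G42540 (4.1 to 364, log2 6.45 ± 0.66, 4.04 at pc 19.1) and LEA4-5, AT5G06760 (2.55 to 297, log2 6.44 ± 1.19, 3.87 at pc 19.1). Lowest at pc 1 were ROXY2, AT5G14070 (51.4 to 1.75, log2 -4.23 ± 0.55, -1.75 at pc 19.1), PR-1-LIKE, AT2G19990 (33.8 to 0.9, log2 -4.22 ± 0.72, -1.39 at pc 19.1) and CYP71B22, AT3G26200 (57.6 to 1.9, log2 -4.22 ± 0.64, -1.78 at pc 19.1). Mitochondrial genes rose (11 of 14 higher, 12 higher adjusted over the list alone, median 1.84, adjusted p = 3.23e-05), with 25S readings from 28.5 and 71.3 to 2637 and 2762.5 on the same arrays, and with matR (55.6 to 765, log2 3.82 ± 0.33) and nad9 (68.7 to 739.5, log2 3.41 ± 0.61), a maturase and a complex I subunit. The actin ratio went from 0.98 and 1.07 to 0.84 and 0.73, and ubiquitin from 0.09 and -0.001 to 0.16 and 0.26. Seed-reserve mobilisation rose (3 of 3 higher, median 0.95, adjusted p = 0.00743), and ABA-responsive effectors did so narrowly (2 of 4 higher, median 0.93, adjusted p = 0.0496). Calvin cycle genes (3 of 3 lower, median -0.92, adjusted p = 0.0164, adjusted p = 0.0945 after quantile normalization) and photorespiration (3 of 3 lower, median -0.91, adjusted p = 0.0327, adjusted p = 0.169 after quantile normalization) fell. An estimated correlation gave, in order, adjusted p = 0.355, 0.0934, 0.301, 0.258 and 0.258. Glucosinolate synthesis did not pass as a group (1 higher and 2 lower of 4, median -1.13, adjusted p = 0.12) although BCAT4 (904 to 139, log2 -2.69 ± 0.24) was lower. The defensin branch did not pass (1 higher and 2 lower of 3, median -3.77, adjusted p = 0.325). Expansins and XTHs did not pass (2 higher and 3 lower of 5, median -1.38, adjusted p = 0.38), with XTH19, AT4G30290 (94.3 to 628, log2 2.74 ± 0.26) higher and EXPA8, AT2G40610 (459 to 47.2, log2 -3.23 ± 0.61, -2.82 at pc 19.1) lower. By limma 3125 probe sets were higher and 2528 lower (2633 and 2870 after quantile normalization), and the total became 3001 without WT blue rep 1 and 3086 without WT ABA rep 1. Quantile normalization lowered the median log2 by 0.10.

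In atmyc2, ABA raised mitochondrial genes (7 of 14 higher, median 1.31, adjusted p = 1.14e-04) and seed-reserve mobilisation (2 of 3 higher, median 0.49, adjusted p = 0.0156). Read with an estimated correlation, these lists gave adjusted p = 0.41 and 0.139. The 25S readings went from 52.2 and 34.1 to 1970.1 and 2561. ABA lowered the Calvin cycle (2 of 3 lower, 3 lower adjusted over the list alone, median -0.88, adjusted p = 0.0281, adjusted p = 0.0674 after quantile normalization) and photorespiration (2 of 3 lower, 3 lower adjusted over the list alone, median -0.70, adjusted p = 0.0443, adjusted p = 0.121 after quantile normalization). Estimating the correlation instead gave adjusted p = 0.316 and 0.316. Plastid-encoded genes (5 higher and 1 lower of 67, none adjusted over the list alone, median 0.27, adjusted p = 0.219 and 0.0121 after quantile normalization), the defensin branch (1 higher and 2 lower of 3, median -4.44, adjusted p = 0.376) and expansins and XTHs (2 higher and 2 lower of 5, median -0.64, adjusted p = 0.676) did not pass in atmyc2. By limma 1741 probe sets were higher and 1791 lower, and the total became 5904 with only the arrays compared, 1706 without atmyc2 blue rep 1, 2008 without atmyc2 ABA rep 1 and 1500 without atmyc2 ABA rep 2.

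In cop1-6, ABA-responsive effectors rose (3 of 4 higher, median 1.86, adjusted p = 0.00317, adjusted p = 0.107 with an estimated correlation). Mitochondrial genes passed as higher (3 of 14 higher, 5 higher adjusted over the list alone, median 0.60, adjusted p = 0.00317, adjusted p = 0.54 with an estimated correlation), though not without cop1-6 ABA rep 2 (adjusted p = 0.441, with the direction reversed). Their median signal was 58.4 and 66 on the blue light arrays and 39.7 and 194 with ABA. The 25S readings went from 52 and 96.3 to 769.5 and 1669. Seed-reserve (1 of 3 higher, median 0.37, adjusted p = 0.0324) and flavonoid genes (1 of 7 higher, median 1.37, adjusted p = 0.0324) passed as well. The list calls became adjusted p = 0.119 and 0.405 with an estimated correlation. Falling groups in cop1-6 were the Calvin cycle (3 of 3 lower, median -1.32, adjusted p = 0.00176) and photorespiration (3 of 3 lower, median -1.0, adjusted p = 0.00317). Photosystem core (3 of 4 lower, 4 lower adjusted over the list alone, median -0.55, adjusted p = 0.0101) and antenna genes (2 of 3 lower, median -0.76, adjusted p = 0.0267) fell as well. An estimated correlation gave, in order, adjusted p = 0.107, 0.107, 0.125 and 0.154. Seed-reserve, flavonoid and antenna genes lost their list calls without cop1-6 ABA rep 1 (adjusted p = 0.0706, 0.483 and 0.0583). The double mutant gained ABA-responsive effectors (3 of 4 higher, median 2.15, adjusted p = 0.015), flavonoid (4 of 7 higher, 5 higher adjusted over the list alone, median 2.12, adjusted p = 0.0156) and seed-reserve transcripts (1 of 3 higher, 2 higher adjusted over the list alone, median 0.56, adjusted p = 0.0224). Tested with an estimated correlation, these lists gave adjusted p = 0.172, 0.2 and 0.172. It lost Calvin cycle (2 of 3 lower, 3 lower adjusted over the list alone, median -1.07, adjusted p = 0.0224) and photosystem core transcripts (3 of 4 lower, 4 lower adjusted over the list alone, median -0.59, adjusted p = 0.0224). Photorespiration fell in it (2 of 3 lower, median -1.10, adjusted p = 0.0328). An estimated correlation gave adjusted p = 0.193 for each list. Auxin response (3 of 5 higher, median 1.74, adjusted p = 0.145) and plastid-encoded genes (3 higher and 3 lower of 67, 1 higher and 2 lower adjusted over the list alone, median -0.28, adjusted p = 0.335) did not pass. By limma 950 probe sets were higher and 1228 lower in cop1-6, and the total became 1086 without cop1-6 blue rep 1, 1156 without cop1-6 blue rep 2 and 1088 without cop1-6 ABA rep 1, and 19 with only the arrays compared. In the double mutant the counts were 1608 and 2168, and the total became 2317 without atmyc2 cop1-6 ABA rep 1 and 1999 without atmyc2 cop1-6 ABA rep 2.

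The ABA responses of the mutants were then set against that of WT. The change of mitochondrial genes with ABA lay below that of WT in the double mutant (8 of 14 below 0, 10 below 0 adjusted over the list alone, median -2.13, adjusted p = 7.56e-07), for instance nad9 (-3.92 ± 0.86) and matR (-2.83 ± 0.46), and in cop1-6 (1 of 14 below 0, median -1.04, adjusted p = 0.0231), for instance matR (-2.73 ± 0.46). Camera gave adjusted p = 0.398 and 0.917 with an estimated correlation. The cop1-6 list call was lost without cop1-6 ABA rep 1 (adjusted p = 0.771). The median mitochondrial signal on the ABA arrays was 118 and 138 in WT, 74.5 and 75.9 in atmyc2, 39.7 and 194 in cop1-6, and 30.4 and 31.6 in the double mutant, where it was 59.8 and 69.4 in blue light. There nad9 went from 143 to 98.7. The 25S readings of the same arrays were 2637 and 2762.5, 1970.1 and 2561, 769.5 and 1669, and 1601 and 1434. Glucosinolate synthesis lay above the WT response in atmyc2 (0 of 4 past the test, 2 at an unadjusted p under 0.05, 1 above 0 adjusted over the list alone, median 1.15, adjusted p = 5.05e-05). Read with an estimated correlation, the list gave adjusted p = 0.116. It did so in the double mutant as well (2 of 4 above 0, median 1.13, adjusted p = 0.0332, adjusted p = 0.0524 after quantile normalization), where GSTU20 went from 242 to 524 and in WT from 580.3 to 147. Estimating the correlation instead gave adjusted p = 0.398. Expansins and XTHs did not pass in the double mutant (2 above 0 and 1 below 0 of 5, 2 above 0 and 2 below 0 adjusted over the list alone, median -0.99, adjusted p = 0.755, with a mean log2 of -0.20 and a list test pointing upward). By limma 0 probe sets differed for atmyc2, with 588 at an unadjusted p under 0.05 (2 at pc 19.1, 1 with a replicate block and 1 with only the arrays compared). For cop1-6, 491 were above and 596 below the WT response (654 and 587 after quantile normalization), and the total became 14 with only the arrays compared, 272 without WT blue rep 1, 2610 without WT blue rep 2, 245 without cop1-6 blue rep 1, 239 without WT ABA rep 1, 366 without WT ABA rep 2 and 1973 without cop1-6 ABA rep 2. For the double mutant the counts were 628 and 873, and the total became 977 with only the arrays compared, 485 without WT blue rep 1, 2442 without WT blue rep 2, 851 without atmyc2 cop1-6 blue rep 2, 432 without WT ABA rep 1, 497 without WT ABA rep 2, 687 without atmyc2 cop1-6 ABA rep 1 and 461 without atmyc2 cop1-6 ABA rep 2. Quantile normalization moved the median log2 from -0.148 to -0.034. nad9 lost its call without WT blue rep 1 (adjusted p = 0.0574), without WT ABA rep 1 (adjusted p = 0.0543) and without atmyc2 cop1-6 ABA rep 2 (adjusted p = 0.0541). GSTU20 lost its call without 6 of the 8 arrays (adjusted p up to 0.0845), and its fall in WT whichever of 4 was left out (adjusted p up to 0.0691).

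**Figure D2:**
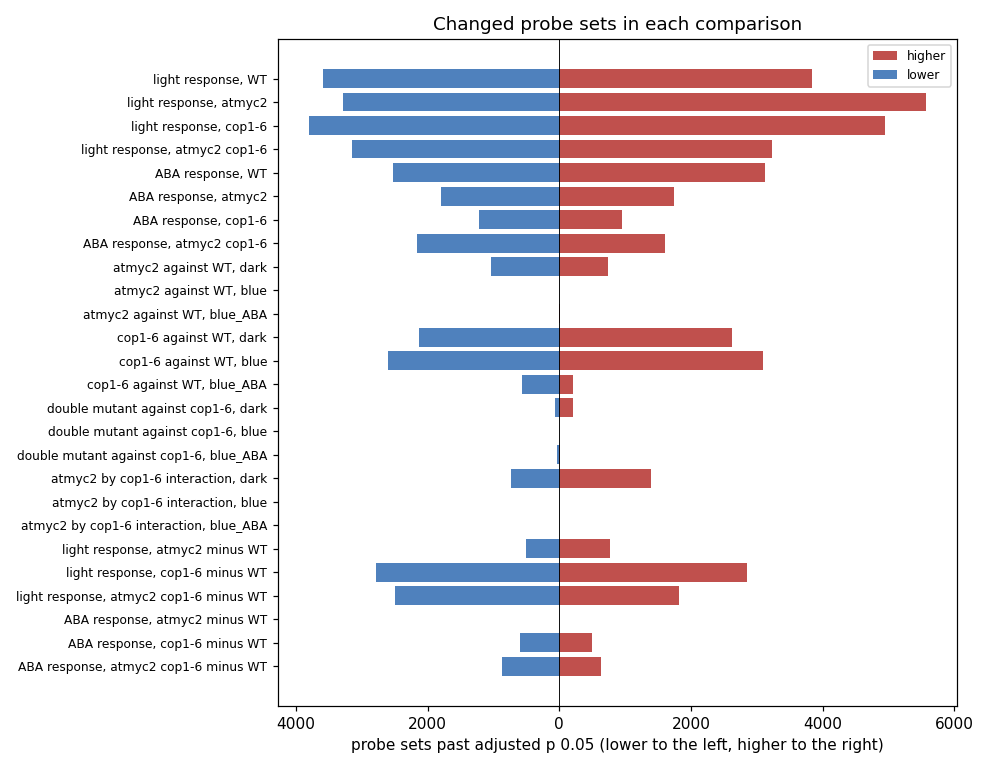
Probe sets past an adjusted p of 0.05 in each comparison by limma, higher to the right and lower to the left. Differences of responses and interactions are drawn as above or below 0.

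**Figure D3:**
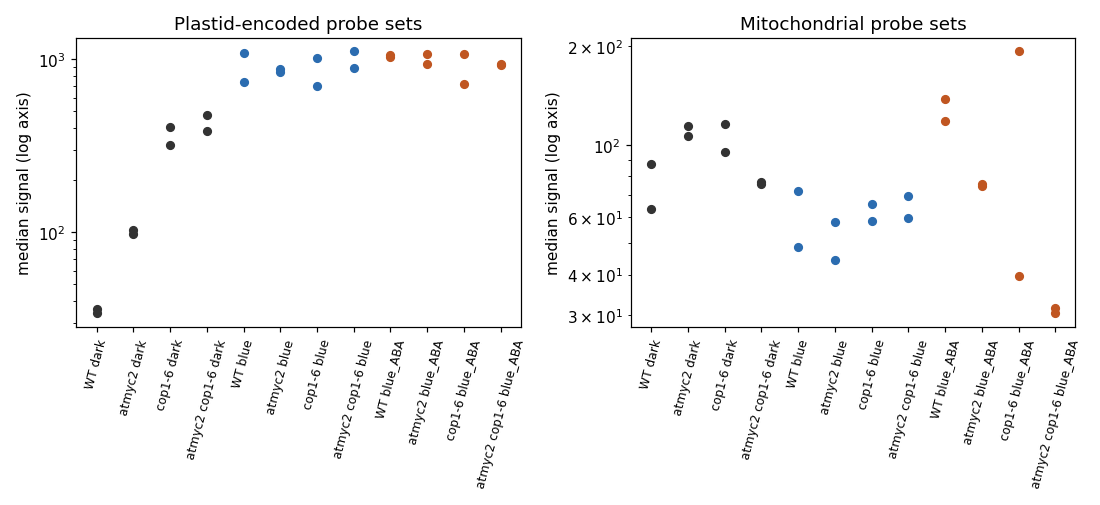
Median signal of the plastid-encoded (left) and mitochondrial probe sets (right) on each array, by group, on log axes.

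What the loss of AtMYC2 changed was asked in each condition, first in darkness. Plastid-encoded genes were higher in dark-grown atmyc2 than in WT (37 of 67 higher, 42 higher adjusted over the list alone, median 1.07, adjusted p = 1.2e-33, adjusted p = 0.0389 with an estimated correlation). The GAPDH ratio separated the same arrays, at -0.32 and -0.33 in WT and -0.001 and 0.005 in atmyc2. The photosystem II gene psbK, ArthCp005 (119 to 1269.6, log2 3.41 ± 0.53) and the NDH subunit gene ndhA, ArthCp079 (26.7 to 256, log2 3.3 ± 0.23, adjusted p = 1.24e-07) rose most. The cytochrome b6f gene petG, ArthCp041 (4.25 to 37.1, log2 2.87 ± 0.37, 1.26 at pc 19.1), the photosystem I gene psaC, ArthCp075 (38.7 to 273, log2 2.86 ± 0.47) and M10, AT2G41280 (2.65 to 24.9, log2 2.82 ± 0.79, 1.01 at pc 19.1) completed the highest 5. The Calvin cycle was lower (2 of 3 lower, 3 lower adjusted over the list alone, median -0.65, adjusted p = 0.015), with PRK (120.1 to 35.8, log2 -1.72 ± 0.22) and SBPASE (38.8 to 24.3, log2 -0.65 ± 0.20), while nuclear photosystem core genes did not move as a group (1 higher and 2 lower of 4, median -0.39, adjusted p = 0.57). In the same test with an estimated correlation, adjusted p = 0.309. The named genes with the lowest folds at pc 1 lay below the dim level in both groups, and PRK fell more at pc 19.1 (-1.34). They were MYR2, AT3G04030 (16.1 to 1.95, log2 -2.73 ± 0.69, -0.74 at pc 19.1) and KICP-02, AT3G50240 (11.1 to 0.9, log2 -2.70 ± 0.40, -0.59 at pc 19.1). Next at pc 1 were the small heat shock protein gene ATHSP22.0, AT4G10250 (13.5 to 1.7, log2 -2.49 ± 0.72, -0.64 at pc 19.1), the receptor kinase gene EFR, AT5G20480 (7.65 to 0.6, log2 -2.44 ± 0.58, -0.44 at pc 19.1) and BGLU19, AT3G21370 (8.35 to 1.05, log2 -2.17 ± 0.65, -0.44 at pc 19.1). By limma 736 probe sets were higher and 1042 lower (706 and 670 after quantile normalization), and the total became 826 without WT dark rep 1, 1003 without WT dark rep 2, 822 without atmyc2 dark rep 1 and 745 without atmyc2 dark rep 2, and 2725 with only the arrays compared. M10, EFR and BGLU19 lost their calls whichever of the 4 arrays was left out (adjusted p from 0.101 to 0.133, 0.0504 to 0.0693 and 0.0696 to 0.206). MYR2 and ATHSP22.0 lost their calls without WT dark rep 1 (adjusted p = 0.12 and 0.0673). SBPASE and ATHSP22.0 lost their calls without WT dark rep 2 (adjusted p = 0.304 and 0.18). SBPASE, MYR2 and ATHSP22.0 lost their calls without atmyc2 dark rep 2 (adjusted p = 0.321, 0.18 and 0.238).

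In blue light few probe sets passed between atmyc2 and WT. The probe sets that passed, named here after their values were seen, were the marker probe set and AT2G02410 (0.95 to 16.1, log2 3.11, 0.80 at pc 19.1). Plastid-encoded genes were slightly lower as a group in atmyc2 (0 of 67 past the test, 6 at an unadjusted p under 0.05, median -0.21, adjusted p = 8.16e-05, adjusted p = 0.819 after quantile normalization). The list call became adjusted p = 0.571 with an estimated correlation. So were photosystem core (0 of 4 past the test, 3 at an unadjusted p under 0.05, median -0.35, adjusted p = 0.00325, adjusted p = 0.819 after quantile normalization) and antenna genes (0 of 3 past the test, 1 at an unadjusted p under 0.05, median -0.38, adjusted p = 0.00833, adjusted p = 0.311 after quantile normalization). An estimated correlation gave adjusted p = 0.195 and 0.195. Mitochondrial genes were also lower (0 of 14 past the test, 1 at an unadjusted p under 0.05, median -0.29, adjusted p = 0.0182, adjusted p = 0.0552 after quantile normalization). With an estimated correlation the list test gave adjusted p = 0.571. With ABA, BCAT4 (139 to 411, log2 1.55 ± 0.24, adjusted p = 0.0182) was higher in atmyc2, and glucosinolate synthesis was higher (1 of 4 higher, 3 higher adjusted over the list alone, median 1.11, adjusted p = 2.78e-09). Tested with an estimated correlation, the list gave adjusted p = 0.0151. Mitochondrial (0 of 14 past the test, 2 at an unadjusted p under 0.05, 1 lower adjusted over the list alone, median -0.81, adjusted p = 2.29e-11) and plastid-encoded genes (0 of 67 past the test, 1 at an unadjusted p under 0.05, median -0.16, adjusted p = 2.94e-05, adjusted p = 0.196 after quantile normalization) were lower with ABA. The list test gave adjusted p = 0.267 and 0.886 with an estimated correlation. The other probe sets that passed with ABA, again seen first, were AT5G19110 (log2 -2.71), AT1G66100 (-4.02, -2.66 at pc 19.1), the marker probe set and a pair without a gene (1.61 and 1.93). By limma 1 probe set was higher and 1 lower in blue light, against 0 and 1 after quantile normalization, and 1729 stood at an unadjusted p under 0.05. The total was 0, with 497 at an unadjusted p under 0.05, without WT blue rep 1, 840 without WT blue rep 2, 1 without atmyc2 blue rep 1 and 1 without atmyc2 blue rep 2. With ABA 3 were higher and 3 lower, with 561 at an unadjusted p under 0.05, and the total was 0, with 447 at an unadjusted p under 0.05, without WT ABA rep 1, 0, with 296 at an unadjusted p under 0.05, without WT ABA rep 2, 0, with 329 at an unadjusted p under 0.05, without atmyc2 ABA rep 1 and 2 without atmyc2 ABA rep 2. With only the arrays compared, the total was 0 in blue light, with 729 at an unadjusted p under 0.05, and 663 with ABA. Other settings gave 1 to 6 in blue light and 3 to 11 with ABA. BCAT4 lost its call whichever of the 4 arrays was left out (adjusted p from 0.0905 to 0.507).

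The cop1-6 mutant was compared with WT to ask what COP1 holds back in darkness. Photosynthesis genes were higher in dark-grown cop1-6 than in dark-grown WT. ECS1 (0.9 to 315, log2 7.43 ± 0.37, 4.06 at pc 19.1, adjusted p = 2.5e-10) ranked highest at pc 1. It was followed by the plastid-encoded ndhG, ArthCp077 (3.35 to 196, log2 5.83 ± 0.62, 3.21 at pc 19.1), atpF (9.65 to 405, log2 5.20 ± 0.29, 3.83 at pc 19.1), ndhJ, ArthCp025 (8.3 to 198, log2 4.95 ± 0.58, 3.03 at pc 19.1) and atpA, ArthCp007 (69.9 to 2137, log2 4.92 ± 0.17) of the NDH complex and ATP synthase. Plastid-encoded genes were higher as a whole (58 of 67 higher, median 2.97, adjusted p = 7.15e-39, adjusted p = 0.0115 with an estimated correlation). Nuclear photosystem core genes (4 of 4 higher, median 2.77, adjusted p = 6.29e-08) rose with PSAN (40.8 to 696, log2 4.06 ± 0.15), and chlorophyll synthesis (7 of 7 higher, median 1.42, adjusted p = 6.07e-06) with HEME2 (35.5 to 122, log2 1.73 ± 0.20). Camera gave adjusted p = 0.0111 and 0.0392 with an estimated correlation. The Calvin cycle (3 of 3 higher, median 2.02, adjusted p = 1.62e-04) rose with SBPASE (38.8 to 233, log2 2.56 ± 0.20). Read with an estimated correlation, the list gave adjusted p = 0.0392. Glucosinolate synthesis (3 of 4 higher, median 2.34, adjusted p = 0.00293) rose with BCAT4 (53.3 to 367, log2 2.81 ± 0.24), and photorespiration (2 of 3 higher, median 1.05, adjusted p = 0.0234) with HPR (179 to 1053, log2 2.55 ± 0.21). Estimating the correlation instead gave adjusted p = 0.129 and 0.134. Lowest at pc 1 were UGT72E3, AT5G26310 (29.8 to 3.55, log2 -3.08 ± 0.92, -1.12 at pc 19.1), ATSBT5.2 (875 to 114, log2 -2.93 ± 0.26, -2.75 at pc 19.1) and NET2D, AT2G22560 (23.6 to 2.55, log2 -2.88 ± 0.58, -0.98 at pc 19.1). Then came RSU1 (38.5 to 5.75, log2 -2.81 ± 0.88, -1.22 at pc 19.1) and NAI2, AT3G15950 (1498 to 218, log2 -2.79 ± 0.28), the last a component of endoplasmic reticulum bodies. Expansins and XTHs did not pass as a group (3 of 5 lower, median -0.85, adjusted p = 0.0754), though EXPA4 (1556 to 549.7, log2 -1.49 ± 0.31) was lower. By limma 2616 probe sets were higher and 2132 lower, and the total became 3078 without WT dark rep 2 and 3057 with only the arrays compared. The dark poly-A controls differed between the same arrays (640.3 and 624 in WT, 215 and 181 in cop1-6). So did the GAPDH ratio (-0.32 and -0.33 in WT, -0.10 and -0.06 in cop1-6) and the actin ratio (0.68 and 1.0 in WT, 1.34 and 1.05 in cop1-6). UGT72E3 and RSU1 lost their calls without WT dark rep 1 (adjusted p = 0.0596 and 0.0661) and without WT dark rep 2 (adjusted p = 0.0929 and 0.126). UGT72E3 lost its call without cop1-6 dark rep 1 (adjusted p = 0.172). RSU1 lost its call without cop1-6 dark rep 2 (adjusted p = 0.207).

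The dark difference of cop1-6 from WT was set beside the light responses. It correlated with the WT light response across probe sets (r = 0.827, against 0.499 in simulated data with the same shared controls, covariance 0.966 against 0.0752 simulated). Both comparisons called 3857 probe sets, 3833 in the same direction. Of these 2216 were higher (620.4 for independent lists) and 1617 lower (473.5) in both. Part of the excess may come from the dark WT arrays shared by both. Against the light response of atmyc2, sharing no array, r was 0.595 (0.000334 simulated, covariance 0.759). Of 3348 probe sets called in both, 3001 had the same direction, 1904 higher (900.3) and 1097 lower (432.6). A preparation effect could still run alike in both, as poly-A signals were highest in dark WT and atmyc2. Genes are not independent replicates in any of these figures. The atmyc2 effect was also compared between the WT and cop1-6 backgrounds. In darkness r was -0.198, but -0.022 without cop1-6 dark rep 1. There 43 probe sets were called in both backgrounds and 30 of them had opposite directions, 28 being lower in atmyc2 and higher in the double mutant where independent lists would share 13.6. In blue light r was -0.0878, with 0.0218 without WT rep 1, 0.0111 without atmyc2 rep 2, 0.0492 without double mutant rep 1, -0.146 without atmyc2 rep 1 and -0.161 without double mutant rep 2. With ABA r was 0.308, but 0.147 without the dim filter and 0.136 without cop1-6 ABA rep 2.

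In blue light, the alpha-amylase gene AMY1, AT4G25000 (14.4 to 496, log2 5.02 ± 0.37, 3.93 at pc 19.1, adjusted p = 3.5e-07) rose most in cop1-6. It was followed by JRG21, AT3G55970 (29.4 to 647, log2 4.47 ± 0.98) and SAG29, AT5G13170 (6.3 to 86.5, log2 3.6 ± 0.84, 2.06 at pc 19.1), the cold-regulated COR15A (4.1 to 43.7, log2 3.44 ± 0.66, 1.45 at pc 19.1) and the xyloglucan endotransglucosylase gene XTH18, AT4G30280 (60.7 to 586, log2 3.41 ± 0.60). Expansin EXPA8 (459 to 38.8, log2 -3.75 ± 0.61) and the kinase gene WAG2, AT3G14370 (54.3 to 3.3, log2 -3.77 ± 0.53, -1.71 at pc 19.1, adjusted p = 5.69e-05) fell. The other genes of the lowest 5 were ATPMEPCRD, AT2G43050 (150.2 to 7.45, log2 -4.25 ± 0.45, -2.68 at pc 19.1), P1R3, AT3G29370 (30.0 to 2.1, log2 -3.34 ± 0.44, -1.2 at pc 19.1) and RALFL27, AT3G29780 (26.3 to 2.95, log2 -2.99 ± 0.83, -1.04 at pc 19.1). Flavonoid and anthocyanin genes held 4 called members without passing as a group (4 of 7 higher, median 2.65, adjusted p = 0.0531), among them UF3GT, AT5G54060 (3.75 to 43, log2 3.26 ± 0.72, 1.44 at pc 19.1) and DFR, AT5G42800 (11.5 to 83.2, log2 2.74 ± 0.66, 1.71 at pc 19.1). Seed-reserve mobilisation was also called by member and not as a group (3 of 3 higher, median 0.90, adjusted p = 0.0613), with ICL (19.8 to 107, log2 2.49 ± 0.62). Chlorophyll synthesis did not pass (3 of 7 lower, median -0.47, adjusted p = 0.0531), though PORB, AT4G27440 (571 to 339, log2 -0.74 ± 0.19) was lower. Among antenna genes (1 higher and 2 lower of 3, median -0.64, adjusted p = 0.537), LHCB4.3, AT2G40100 (176 to 426, log2 1.27 ± 0.19) was higher and LHCB4.2 (2557 to 1167, log2 -1.10 ± 0.21) lower. Expansins and XTHs (2 higher and 3 lower of 5, median -2.06, adjusted p = 0.153) and plastid-encoded genes (2 higher and 4 lower of 67, none adjusted over the list alone, median -0.25, adjusted p = 0.113 and 0.95 with the direction reversed after quantile normalization) did not pass either. By limma 3086 probe sets were higher and 2610 lower (2666 and 2817 after quantile normalization), and the total became 2516 without WT blue rep 1 and 3094 without cop1-6 blue rep 1. RALFL27 lost its call without WT blue rep 1 (adjusted p = 0.0904). RALFL27 and DFR lost their calls without cop1-6 blue rep 1 (adjusted p = 0.128 and 0.0534). ICL lost its call without WT blue rep 2 (adjusted p = 0.0607).

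With ABA, anthocyanin genes were higher in cop1-6 than in WT. Among them UF3GT (10.4 to 179, log2 3.88 ± 0.72, 2.66 at pc 19.1), DFR (19 to 266, log2 3.66 ± 0.66, 2.84 at pc 19.1) and CHIL, AT5G05270 (12 to 77.1, log2 2.48 ± 0.57, 1.56 at pc 19.1) ranked highest. Flavonoid and anthocyanin genes were higher as a whole (4 of 7 higher, 6 higher adjusted over the list alone, median 2.48, adjusted p = 6.39e-07, adjusted p = 0.0661 with an estimated correlation). The other genes of the highest 5 were LPR1, AT1G23010 (16.3 to 93.7, log2 2.43 ± 0.31, 1.65 at pc 19.1) and BGLU33, AT2G32860 (19.6 to 58.8, log2 1.48 ± 0.39). EXPA8 (47.2 to 2.45, log2 -3.89 ± 0.61, -1.61 at pc 19.1, adjusted p = 0.00143) fell, as did the auxin gene IAA20, AT2G46990 (24.1 to 2.7, log2 -2.76 ± 0.56, -0.99 at pc 19.1). The other falls of the lowest 5 were those of JKD, AT5G03150 (15.3 to 1.15, log2 -2.68 ± 0.49, -0.72 at pc 19.1), PDF2.5, AT5G63660 (8.3 to 0.5, log2 -2.63 ± 0.58, -0.48 at pc 19.1) and P1R3 (21.2 to 3, log2 -2.54 ± 0.44, -0.86 at pc 19.1). Expansins and XTHs were lower as a group (1 of 5 lower, 3 lower adjusted over the list alone, median -0.86, adjusted p = 0.00425, adjusted p = 0.0661 with an estimated correlation). So were chlorophyll synthesis (2 of 7 lower, 3 lower adjusted over the list alone, median -0.33, adjusted p = 0.0172) with PORB (539 to 281, log2 -0.94 ± 0.19), and plastid-encoded genes (4 of 67 lower, median -0.45, adjusted p = 5.05e-07) with psbA, ArthCp002 (1044 to 366, log2 -1.53 ± 0.34). In the same test with an estimated correlation, adjusted p = 0.256 and 0.256. Photosystem core (0 of 4 past the test, 3 at an unadjusted p under 0.05, median -0.39, adjusted p = 0.0254) and mitochondrial genes (0 of 14 past the test, 4 at an unadjusted p under 0.05, median -0.77, adjusted p = 0.00392) passed as lower with no single member past the test. The list calls became adjusted p = 0.256 and 0.439 with an estimated correlation. Over all 23 probe sets, the median mitochondrial signal was 118 and 138 in WT and 39.7 and 194 in cop1-6. Without cop1-6 ABA rep 1 the list calls of chlorophyll synthesis, plastid-encoded, photosystem core and mitochondrial genes were lost (adjusted p = 0.101, 0.229, 0.229 and 0.101), the last with the direction reversed. Expansins and XTHs lost theirs without cop1-6 ABA rep 2 (adjusted p = 0.0522). By limma 213 probe sets were higher and 572 lower, and the total became 308 without WT ABA rep 1, 156 without WT ABA rep 2 and 1721 without cop1-6 ABA rep 2. With only these 4 arrays fitted the total was 0, with 2261 at an unadjusted p under 0.05, and these cop1-6 replicates had the lowest correlation of all pairs. CHIL, BGLU33, IAA20, PDF2.5, PORB and psbA lost their calls without WT ABA rep 1 (adjusted p = 0.0835, 0.0994, 0.069, 0.0891, 0.0509 and 0.0557). CHIL, BGLU33, IAA20, JKD, PDF2.5, P1R3, PORB and psbA lost their calls without WT ABA rep 2 (adjusted p = 0.159, 0.317, 0.0724, 0.111, 0.0929, 0.0579, 0.0783 and 0.163). CHIL, BGLU33 and psbA lost their calls without cop1-6 ABA rep 1 (adjusted p = 0.146, 0.308 and 0.0958).

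The double mutant was set against cop1-6 to ask what AtMYC2 changes in the cop1-6 background. In darkness WRKY53, AT4G23810 (11.9 to 52.3, log2 2.04 ± 0.32, 1.2 at pc 19.1), a transcription factor gene, and the subtilase gene SBT3.3, AT1G32960 (1.75 to 11.1, log2 2.24 ± 0.55, 0.53 at pc 19.1) were higher in the double mutant. The other higher ones were CCOAMT, AT1G67980 (6.25 to 54.5, log2 2.99 ± 0.68, 1.53 at pc 19.1), SECA2, AT1G21650 (2.25 to 12.8, log2 2.33 ± 0.53, 0.58 at pc 19.1) and CYP71B23, AT3G26210 (26.6 to 107, log2 2.01 ± 0.40). The photosystem II gene psbA (1111 to 429, log2 -1.39 ± 0.34, adjusted p = 0.0441), PRA1.B6, AT5G07110 (149 to 70.8, log2 -1.07 ± 0.20) and STR18, AT5G66170 (412 to 192, log2 -1.03 ± 0.25) were lower. Mitochondrial (0 of 14 past the test, 0 at an unadjusted p under 0.05, median -0.57, adjusted p = 0.0154) and antenna genes (0 of 3 past the test, 3 at an unadjusted p under 0.05, 3 lower adjusted over the list alone, median -0.45, adjusted p = 0.047, adjusted p = 0.0947 after quantile normalization) were lower as groups in darkness. An estimated correlation gave adjusted p = 0.717 and 0.357. By limma 211 probe sets were higher and 59 lower in darkness (96 and 30 after quantile normalization), and the total became 412 at pc 19.1, 169 with only the arrays compared, 26 without cop1-6 dark rep 1, 1454 without cop1-6 dark rep 2, 9 without atmyc2 cop1-6 dark rep 1 and 48 without atmyc2 cop1-6 dark rep 2. CCOAMT lost its call whichever of the 4 arrays was left out (adjusted p from 0.0653 to 0.287). SBT3.3, SECA2, CYP71B23, psbA, PRA1.B6 and STR18 lost their calls without cop1-6 dark rep 1 (adjusted p = 0.383, 0.351, 0.236, 0.287, 0.0573 and 0.46) and without atmyc2 cop1-6 dark rep 2 (adjusted p = 0.197, 0.125, 0.0819, 0.217, 0.0993 and 0.137). WRKY53, SBT3.3, SECA2, CYP71B23, psbA, PRA1.B6 and STR18 lost their calls without atmyc2 cop1-6 dark rep 1 (adjusted p = 0.104, 0.256, 0.277, 0.203, 0.198, 0.106 and 0.318).

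In blue light the probe sets that differed between the double mutant and cop1-6, named after their values were seen, were AT5G19110 (74.2 to 10.6, log2 -2.79, -1.66 at pc 19.1), AT1G27670 (1.35 to 12.7, log2 2.36, 0.61 at pc 19.1) and the marker probe set. With ABA, SBT4.12, AT5G59090 (18.9 to 2.2, log2 -2.52 ± 0.41, -0.79 at pc 19.1) and THI2.2, AT5G36910 (9.6 to 1.5, log2 -2.05 ± 0.39, -0.47 at pc 19.1), a subtilase and a thionin gene, were lower. Mitochondrial genes were lower as a group (0 of 14 past the test, 9 at an unadjusted p under 0.05, 4 lower adjusted over the list alone, median -1.14, adjusted p = 2.13e-07). With an estimated correlation the list test gave adjusted p = 0.309. Glucosinolate synthesis was higher (0 of 4 past the test, 4 at an unadjusted p under 0.05, 4 higher adjusted over the list alone, median 0.76, adjusted p = 2.6e-05, adjusted p = 0.117 with an estimated correlation). Chlorophyll synthesis (0 of 7 past the test, 2 at an unadjusted p under 0.05, median 0.29, adjusted p = 0.00366) and the Calvin cycle (0 of 3 past the test, 1 at an unadjusted p under 0.05, 1 higher adjusted over the list alone, median 0.28, adjusted p = 0.0422, adjusted p = 0.0805 after quantile normalization) were slightly higher. Tested with an estimated correlation, these lists gave adjusted p = 0.309 and 0.309. Mitochondrial genes lost their list call without cop1-6 ABA rep 2 (adjusted p = 0.77). Chlorophyll synthesis and the Calvin cycle lost theirs without cop1-6 ABA rep 1 (adjusted p = 0.187 and 0.984). By limma the counts in blue light were 1 and 2, with 1006 at an unadjusted p under 0.05, against 0 and 1 after quantile normalization, and the total was 6 at pc 19.1, 5 without trend and robust, 14 without cop1-6 blue rep 2 and 50 without atmyc2 cop1-6 blue rep 2. With ABA they were 11 and 30 (21 and 31 after quantile normalization, 40.4% higher against 26.8%), and the total became 25 without trend and robust, 1 with only the arrays compared, 1438 without cop1-6 ABA rep 1, 12 without cop1-6 ABA rep 2, 11 without atmyc2 cop1-6 ABA rep 1 and 14 without atmyc2 cop1-6 ABA rep 2. SBT4.12 and THI2.2 lost their calls without cop1-6 ABA rep 2 (adjusted p = 0.12 and 0.335) and without atmyc2 cop1-6 ABA rep 2 (adjusted p = 0.167 and 0.237). THI2.2 lost its call without atmyc2 cop1-6 ABA rep 1 (adjusted p = 0.138).

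The interaction asked whether the atmyc2 effect was the same with and without cop1-6. In darkness it was below 0 for plastid-encoded genes (1 above 0 and 33 below 0 of 67, 2 above 0 and 38 below 0 adjusted over the list alone, median -1.25, adjusted p = 4.84e-22). The list test gave adjusted p = 0.153 with an estimated correlation. There psbK stood at 119 in WT, 1269.6 in atmyc2, 2638 in cop1-6 and 1428 in the double mutant (log2 interaction -4.28 ± 0.75), with the same direction for psaC (-4.07 ± 0.67) and ndhG (-4.04 ± 0.88, -2.02 at pc 19.1). The dark WT arrays had GAPDH ratios of -0.32 and -0.33. Mitochondrial genes lay below 0 as well (1 of 14 below 0, 2 below 0 adjusted over the list alone, median -0.83, adjusted p = 0.00485, adjusted p = 0.714 with an estimated correlation). In blue light plastid-encoded genes lay above 0 (0 of 67 past the test, 2 at an unadjusted p under 0.05, median 0.32, adjusted p = 6.94e-05, adjusted p = 0.375 after quantile normalization). Camera gave adjusted p = 0.424 with an estimated correlation. Photosystem core genes did so too (0 of 4 past the test, 2 at an unadjusted p under 0.05, 2 above 0 adjusted over the list alone, median 0.51, adjusted p = 0.005, adjusted p = 0.375 after quantile normalization), as did antenna genes (0 of 3 past the test, 2 at an unadjusted p under 0.05, 2 above 0 adjusted over the list alone, median 0.59, adjusted p = 0.00875, adjusted p = 0.207 after quantile normalization). Read with an estimated correlation, these lists gave adjusted p = 0.199 and 0.199. With ABA plastid-encoded genes lay above 0 (0 of 67 past the test, 2 at an unadjusted p under 0.05, median 0.18, adjusted p = 0.0012, adjusted p = 0.315 after quantile normalization). Estimating the correlation instead gave adjusted p = 0.421. Chlorophyll synthesis (0 of 7 past the test, 0 at an unadjusted p under 0.05, median 0.32, adjusted p = 0.0034, adjusted p = 0.0685 after quantile normalization) and antenna genes (0 of 3 past the test, 1 at an unadjusted p under 0.05, median 0.25, adjusted p = 0.0428, adjusted p = 0.247 after quantile normalization) lay above 0 as well. In the same test with an estimated correlation, adjusted p = 0.386 and 0.386. Without cop1-6 ABA rep 1 the list calls with ABA were lost for plastid-encoded genes (adjusted p = 0.805, with the direction reversed), chlorophyll synthesis (adjusted p = 0.217) and antenna genes (adjusted p = 0.331). By limma 1386 probe sets were above 0 and 731 below in darkness (757 and 612 after quantile normalization, 55.3% higher against 65.5%, with the median log2 lowered by 0.13), and the total became 1270 without WT dark rep 1, 1376 without WT dark rep 2, 1179 without atmyc2 dark rep 1, 1123 without atmyc2 dark rep 2, 547 without cop1-6 dark rep 1, 3537 without cop1-6 dark rep 2 and 570 without atmyc2 cop1-6 dark rep 1. In blue light 0 passed, with 1662 at an unadjusted p under 0.05, and the total was 5 without trend and robust, 334 without WT blue rep 2, 1 without atmyc2 blue rep 1 and 11 without atmyc2 cop1-6 blue rep 2. With ABA 0 passed, with 658 at an unadjusted p under 0.05, and the total was 339 without cop1-6 ABA rep 1, 1 without atmyc2 cop1-6 ABA rep 1 and 1 without atmyc2 cop1-6 ABA rep 2. ndhG lost its call without cop1-6 dark rep 1 (adjusted p = 0.0626) and without atmyc2 cop1-6 dark rep 1 (adjusted p = 0.0515).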

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

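The tests of the cop1-6 arrays with ABA and of the poly-A controls were chosen after the results were seen, and both tests of the dark atmyc2 change before.

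Differences between groups drew attention to the following genes, given as log2 differences, with the value at pseudocount 19.1 second where a mean lay under the dim level and the fold differed by more than 1.5 times. The atmyc2 by cop1-6 interaction in darkness covered 2117 probe sets, with EFR (4.58, 0.89), CHI (3.26) and KICP-02 (3.16, 0.76) above 0 and psbK (-4.28), psaC (-4.07) and ndhG (-4.04, -2.02) below. The light response of atmyc2 differed from that of WT at 1286, with EFR (3.21, 0.59), KICP-02 (3.13, 0.81) and XIJ (2.90, 0.65) above and GIS (-3.88, -1.12), M10 (-3.77, -1.15) and psbK (-3.63) below. For cop1-6 the light response differed at 5633, with AMY1 (5.50, 4.13), EFR (5.07, 1.56) and NET1B (4.64, 2.76) above and ECS1 (-8.79, -5.41), ndhG (-6.79, -4.04) and psbB (-6.04, -3.74) below, and for the double mutant at 4301, with AMY1 (4.69, 3.34), UGT73C1 (3.97, 1.49) and BGLU19 (3.89, 0.72) above and ECS1 (-8.91, -5.51), atpF (-5.39, -4.01) and ndhA (-5.17) below. The ABA response differed from that of WT at 1087 in cop1-6, with ATPMEPCRD (3.86, 2.52), MMP (3.64, 0.81) and ORA47 (2.83, 1.16) above and AMY1 (-3.81, -2.81), XTH18 (-3.45) and XIJ (-2.88, -0.67) below. In the double mutant it differed at 1501, with GSTU20 (3.08), PUB19 (2.95, 1.77) and ROXY2 (2.51, 1.35) above and JRG21 (-4.69), AMY1 (-4.48, -3.39) and EXPA18 (-4.36, -1.40) below. With each of the 8 arrays left out in turn, calls were lost in the ABA difference of the double mutant for JRG21 and EXPA18 (7 times), GSTU20 and ROXY2 (6) and PUB19 (5). In that of cop1-6 they were lost for XIJ (7), XTH18 (6), MMP and ORA47 (5), and in the light difference of atmyc2 for XIJ and M10 (7), EFR (6) and psbK (1). In the dark interaction CHI lost its call 6 times and ndhG 2 times. The highest adjusted p was 0.19, for ORA47.

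The cop1-6 arrays with ABA stood apart from each other. The marker, also called in blue light, read 251 on replicate 1 (at most 15 with atmyc2), arguing against a swap with the double mutant. Of 6 ratios of 3 prime to 5 prime control signals, 0 lay outside the range of the other arrays. That range spans all growth conditions, so a smaller sign of RNA degradation cannot be excluded. The GAPDH ratio of replicate 2 (0.03) was the highest of the 8 arrays with ABA, while its actin and ubiquitin ratios were not. A mixture of RNA like replicate 1 with RNA like cop1-6 in blue light was excluded by a count. There 76 probe sets of replicate 2 lay above both sources (at most 14 in the other ABA groups). A weaker exposure of replicate 2 to ABA may be part of the difference, because its slope on the WT response was 0.514 against 0.707 for replicate 1, a gap of 0.193 where other groups reached 0.0573. It would not by itself give the 76 probe sets, and by the same count replicate 1 had 411, while a biological difference between the samples was not tested.

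Control signals differed between conditions: the 25S probe set had a median of 1819.5 with ABA and 56.5 in blue light, and the poly-A controls a median of 601.7 in dark WT and atmyc2 and 8 in blue light. Whether the blue samples could have been labelled without these controls is undecided, since 2 of 32 signals passed the dim level of 19.1, the highest at 20.9. The bound was first any signal above that level and was loosened to 2-fold after this count was seen, and under the first bound the explanation would have been excluded. A difference in sample preparation might have made part of the dark cop1-6 change, which cannot be told, because the poly-A to hybridisation ratios of the 2 sets of dark arrays did not overlap (ratio of the nearest arrays 1.41).

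Many probe sets changed with atmyc2 in darkness (1778) and few in blue light. Equal changes in both, hidden in blue light by spread, were excluded: for probe sets picked on dark replicate 1, the mean signed change was 0.567 on dark replicate 2 and -0.12 in blue light, a ratio of -0.211. A single array as the origin was excluded, since the lowest count with 1 of the 4 arrays left out was 745, without atmyc2 dark replicate 2. An AtMYC2 effect that depends on light remains a hypothesis, found and tested on the same data, and dark and blue arrays also differ in their controls. Other origins stay open, since the GAPDH ratio of 3 prime to 5 prime signals also separated dark WT (log2 -0.32 and -0.33) from dark atmyc2 (-0.001 and 0.005). The actin and ubiquitin ratios did not separate them.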

How the results depend on the processing

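Every alternative was planned before the data were examined except the added families and the list tests without a cop1-6 array with ABA. The causes of the changes below were not tested.

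With only the arrays of the groups compared, counts became 5904 for the ABA response of atmyc2 and 19 for that of cop1-6. Genotype contrasts became 2725 for atmyc2 in darkness, 0 in blue light (limma, 729 at an unadjusted p under 0.05) and 663 with ABA. For cop1-6 they became 3057 in darkness and 0 with ABA (2261 unadjusted), and for the double mutant 169 in darkness and 1 with ABA. Differences from WT became 588 for the light response of atmyc2, and 1, 14 and 977 for the ABA responses of atmyc2, cop1-6 and the double mutant. This setting uses fewer arrays to estimate the spread.

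For atmyc2 in blue light the count was 6 with no pseudocount, 1 with the pseudocount at the 40th percentile, 1 with the filter at the 60th percentile, 1 after quantile normalization and 4 without trend and robust. For atmyc2 with ABA it was 3 with no pseudocount and 11 with the larger one. The larger pseudocount gave 412 for the double mutant in darkness, 6 in blue light, and 2 for the ABA response of atmyc2 minus WT. Quantile normalization gave 126 and 1 for the double mutant in darkness and blue light, 1369 for the dark interaction and 762 for the light response of atmyc2 minus WT. Moderation without trend and robust gave 5 and 25 for the double mutant in blue light and with ABA, and 5 for the blue interaction. Of 100 list calls, 16 held with an estimated correlation and 80 after quantile normalization. With one cop1-6 array with ABA left out, 3 list tests reversed: mitochondrial genes in the ABA response of cop1-6 without replicate 2 (adjusted p = 0.441, against 0.00317 in the main test and 1.71e-17 without replicate 1). The others reversed without replicate 1, namely mitochondrial genes against WT with ABA (0.101, against 0.00392, and 2.96e-13 without replicate 2) and plastid-encoded genes in the interaction with ABA (0.805, against 0.0012, and 2.02e-14 without replicate 2). Without the dim filter the correlation of the atmyc2 effect between backgrounds with ABA was 0.147.

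With 1 array left out, counts ran as follows: light response of double 4195 to 5197, ABA response of WT 3001 to 5990, ABA response of atmyc2 1500 to 2507, ABA response of cop1-6 1086 to 2879, ABA response of double 1999 to 3142, atmyc2 vs WT, dark 745 to 1003, atmyc2 vs WT, blue 0 to 840, atmyc2 vs WT, ABA 0 to 2, cop1-6 vs WT, dark 3078 to 3983, cop1-6 vs WT, blue 2516 to 6042. The rest were cop1-6 vs WT, ABA 156 to 1721, double vs cop1-6, dark 9 to 1454, double vs cop1-6, blue 2 to 50, double vs cop1-6, ABA 11 to 1438, interaction in dark 547 to 3537, interaction in blue 0 to 334, interaction in ABA 0 to 339, light response of atmyc2 minus WT 307 to 3004, ABA response of cop1-6 minus WT 239 to 2610, ABA response of double minus WT 432 to 2442. Where the lowest was 0, the limma counts at an unadjusted p under 0.05 were atmyc2 vs WT, blue 497, atmyc2 vs WT, ABA 447, interaction in blue 704, interaction in ABA 509. A lone array was assumed to vary like the other groups.

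In a model with a replicate block the ABA response of atmyc2 minus WT gave 1, and the block changed no other count by over 1.5 times. Replicate numbers did not pair samples: of 66 pairs of groups, 8 correlated over 0.1, with r from -0.155 to 0.306.

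Of 264 results on named genes, the call was lost in 6 with no pseudocount, 22 with the larger one, 15 without the dim filter, 22 after quantile normalization, 6 with the block, 17 without trend and robust, 57 with only the arrays compared, and 3 of 234 at the 60th percentile. Leaving out arrays lost 307 of 1436. No direction reversed in these settings. Signal near background limits the folds of genes under the dim level and hides changes among the probe sets left out.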

Other observations

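These families were chosen after the annotation was seen and are named after their values were seen. PRA genes, which act in membrane traffic, fell in WT in blue light (8 of 10 lower, median -1.71, adjusted p = 1.25e-05, adjusted p = 0.147 with an estimated correlation). They were lower in dark-grown cop1-6 as well (9 of 10 lower, median -1.22, adjusted p = 1.53e-06, adjusted p = 0.103 with an estimated correlation). In blue light cop1-6 had lower expansins (5 of 8 lower, 6 adjusted over the list alone, median -1.72, adjusted p = 0.00426, adjusted p = 0.309 with an estimated correlation). The beta-glucosidase family BGLU rose with ABA in WT (8 of 11 higher, median 1.09, adjusted p = 0.0235, adjusted p = 0.249 with an estimated correlation). In dark-grown atmyc2 the LSM genes of RNA processing were higher (4 of 6 higher, median 0.80, adjusted p = 2.12e-04, adjusted p = 0.047 with an estimated correlation). The GAPDH ratio was -0.32 and -0.33 in dark WT, -0.06 and -0.09 in WT in blue light, -0.10 and -0.06 in dark cop1-6 and -0.001 and 0.005 in dark atmyc2.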
